A study of Mus musculus with 48 samples.

How the data were processed

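Liver poly(A) RNA of 48 mice was sequenced, in 8 groups of 6 livers that cross sex, diet and exposure. Per the labels' protocols, RNA was extracted with the RNeasy plus mini kit and pre-made libraries were sequenced by Azenta Life Sciences. Per the submitters' processing notes, FastQC, Trimmomatic 0.36, STAR 2.5.2b and DESeq2 were used with the GRCm38 build. The notes list these tools without their order or role. The read counter, the gene annotation, the gene lengths and the strand setting are not given in the sources used here.

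The deposited values are TPM, a share of transcripts corrected for gene length, made by the authors for each library without pooling. TPM divides reads by gene length and scales each library to a shared total. Every column summed to that total (1000000), so the values keep no sequencing depth. The depth of each library is therefore unknown, and no interval or detection limit that needs it was computed. The table held 49315 genes by identifier, of which 174 had a blank name, 191 carried a name shared with another entry and 14110 were at 0 in all libraries. Blank and shared names were replaced by the identifier. Of the 15820 genes tested, 15779 had an identifier found in GENCODE M21, from which coordinates on GRCm38 were taken. They are given as 1-based positions.

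Because the table holds TPM and not counts, the count test that the design kept for counts was not used. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. Genes with at least 1 TPM in at least 6 libraries entered. One model with a mean for each of the 8 groups was fitted to all 48 libraries, with 40 residual degrees of freedom, and 15 comparisons were taken from it. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. A log2 change is a difference of group means of log2(TPM + 1), which understates the change of genes with low TPM. Levels are given as mean TPM ± SD over the 6 livers of a group. Library names number the animals of each diet separately, and whether the diets were run as separate cohorts is not given in the sources used here. A cohort difference would be part of every comparison of diets. The labels describe each library as a replicate of mice of its group and give no batch, so p-values measure the spread between these libraries.

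Gene lists were written before the data were examined. The 42 lists cover nuclear receptor and stress responses, lipid, sterol, sugar and amino acid metabolism, sex-biased liver genes, liver zonation and cell types. Lists with at least 5 measured members were tested, which left 40. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 40 lists, and again with the correlation estimated from the data. The adjusted p with an estimated correlation is given beside the calls, so that it shows which of them hold. Member counts are given over all genes tested and adjusted over the list alone. List names such as targets or markers say how the genes were grouped and carry no claim on their regulation here. Lists overlap in part: 5 genes stand in both the CAR/PXR and female-biased lists, and 6 in both the urea cycle and periportal lists.

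The genes named were fixed by rule. For each comparison these were the 6 with the largest positive and the 6 with the most negative log2 change among called genes with a mean of at least 1 TPM in the higher group, leaving out predicted genes. Added to these were all measured members of the AhR battery for the mixture and, for each called list, the 4 members with the smallest p. Where fewer than 6 genes passed, those that passed were taken. The rule picks large changes in the libraries compared, so a lack of overlap between groups for such genes describes them and adds no support. Some genes that the rule picked are not reported here.

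Alternatives chosen before the data were examined were a trimmed-mean scaling of TPM (30% of log ratios and 5% of abundances trimmed at each end), no filter on low values, a pseudocount of 0.1, a fit of only the groups compared, and the replicate number as a block. An alternative chosen after seeing the data left out 3 libraries that held muscle transcripts. For each comparison 100 splits of the libraries were used, the real one included. In most comparisons other splits called as many lists with the preset correlation, so list calls that rest on it alone describe these libraries and carry little weight. The closing section gives the effects of these choices.

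The procedure was tested on simulated data in which 200 of the 15820 genes were changed by known folds. For the mixture in males on the low-fat diet it recovered 77.6% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls. For the difference of mixture effects between diets in males the shares were 52.2%, 85.1% and 98.5%, with 13 false calls. A simulated shift of 0.4 in log2 of 1 list was called, as was 1 of the 39 lists that were not shifted. The simulated genes varied independently of each other, which genes of real libraries do not. In the real LFD males, other splits of the libraries called a median of 10 lists, up to 18 lists and up to 108 genes. The simulation therefore does not give the false calls to expect in real libraries. Genes of near-identical families (Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Mup, Sult2a and Serpina1) share reads, so the split of values among their members is uncertain. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.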

Results

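Liver transcriptomes were measured by poly(A) RNA sequencing in male and female mice of the inbred strain C57BL/6J. Animals received a low-fat diet (LFD) or a high-fat diet (HFD), together with weekly vehicle or a mixture of dioxin-like compounds, and were sampled after 12 weeks. The mixture held TCDD at 10 ng/kg, PeCDF (a chlorinated dibenzofuran) at 80 ng/kg and PCB126 (a chlorinated biphenyl) at 140 ng/kg. Such compounds bind the aryl hydrocarbon receptor (AhR), a transcription factor that induces cytochrome P450 genes of the Cyp1 family. Each of the 8 groups held 6 livers. The values were TPM, which keep no sequencing depth, and the libraries held between 13180 and 14713 genes at 1 TPM or more. Xist and Ddx3y levels fitted the labelled sex in all 48 libraries, and no pair of libraries was a duplicate, the highest correlation between 2 libraries being 0.984.

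Transcripts of skeletal muscle stood out most in 3 libraries. The summed TPM of 15 muscle genes, a list written after the libraries were seen, was 25913 in replicate 6 of the HFD males given the mixture, 9732 in replicate 3 of the LFD vehicle females and 1977 in replicate 3 of the LFD females given the mixture. The highest of the other 45 libraries had 811 and their median was 28.5. That highest library was replicate 4 of the LFD vehicle males, with all 15 genes above the rest of the 45. Replicate 5 of that group had 380. The female library given the mixture also held 1836 TPM of 6 adrenal cortex genes. Replicate 6 of the LFD males given the mixture held 107 TPM of them, against a median of 9.1 in the 45. All libraries were kept, and values without the 3 are given where a count moved by more than 1.5 times. Leaving out the 3 does not clear other tissue from the LFD males.

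**Figure D1:**
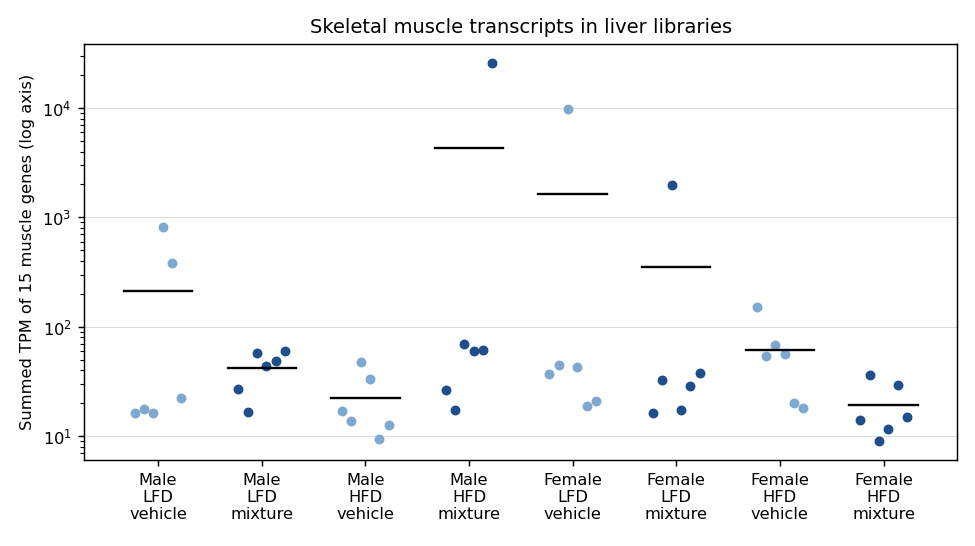
Summed TPM of 15 skeletal muscle genes (log axis) in each liver library by group, with a point per library and a line at the group mean of TPM (n = 6). Single libraries lie at 25913 (HFD males with the mixture), 9732 (LFD vehicle females) and 1977 (LFD females with the mixture), and the other 45 lie at or below 811.

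The first question was which genes the mixture changed in each sex on each diet. Cyp1a1 and Cyp1a2, which encode the xenobiotic-metabolizing P450 enzymes most closely tied to AhR activation, rose in all 4 combinations of sex and diet. On the LFD, Cyp1a1 was at 1.73 ± 0.347 TPM in vehicle males and 139 ± 51.9 with the mixture (SD, n = 6), a log2 change of 5.60 (SE 0.20, limma adjusted p = 1.03e-24). In LFD females it was at 1.79 ± 0.474 and 84.8 ± 17.7 TPM, a log2 change of 4.93 (SE 0.20, adjusted p = 1.74e-22). On the HFD it was at 0.846 ± 0.260 and 4.66 ± 2.47 TPM in males, a log2 change of 1.52 (SE 0.20, adjusted p = 2.43e-05). In HFD females it was at 0.862 ± 0.272 and 3.28 ± 1.02 TPM, a log2 change of 1.18 (SE 0.20, adjusted p = 0.00625). Cyp1a2 stood at a higher level. It went from 669 ± 79.5 to 3172 ± 527 TPM in LFD males and from 320 ± 53.9 to 2297 ± 293 in LFD females. On the HFD it went from 331 ± 77.5 to 1644 ± 306 TPM in males and from 408 ± 45.7 to 2536 ± 263 in females. Its log2 changes were 2.24, 2.85, 2.32 and 2.63 in that order (SE 0.13 each, adjusted p from 2.68e-21 to 3.26e-17). For both genes, all 6 exposed libraries of each combination lay above all 6 of its vehicle libraries. Separate groups of this kind arise by chance for 0.216% of genes. In a fit of HFD males alone, the Cyp1a1 call was lost at the same log2 change (adjusted p = 0.0786).

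**Figure D2:**
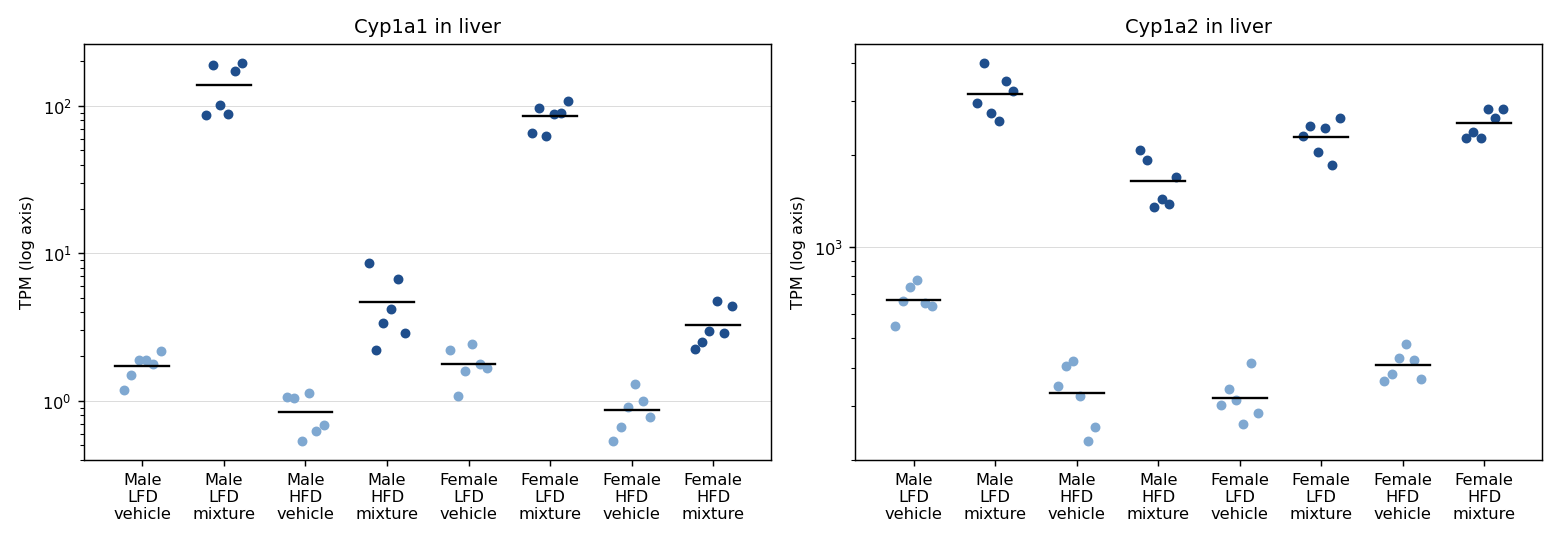
TPM of Cyp1a1 (left) and Cyp1a2 (right) in each liver library on log axes, with a point per library and a line at the group mean (n = 6 per group, light points for vehicle and dark for the mixture). Mean Cyp1a1 with the mixture was 139 and 84.8 TPM in LFD males and females and 4.66 and 3.28 in HFD males and females, while mean Cyp1a2 with the mixture was between 1644 and 3172 TPM in every combination.

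These neighbouring genes lie on chromosome 9 of GRCm38 and are protein coding in GENCODE M21, Cyp1a1 (ENSMUSG00000032315) at 57687928 to 57703824 on the plus strand and Cyp1a2 (ENSMUSG00000032310) at 57676937 to 57683703 on the minus strand. Of the 28 genes of the AhR battery, 25 were measured, and Ahrr, Aldh3a1 and Fabp12 fell short of the filter.

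In LFD males, 6 genes rose with the mixture and 0 fell by limma, with 830 at an unadjusted p under 0.05. Besides the Cyp1a genes they were Cyp3a41a, a P450 expressed mainly in females (log2 change 1.22, SE 0.25, adjusted p = 0.0315), Slc46a3, a lysosomal transporter (0.81, SE 0.15, adjusted p = 0.0116), Htatip2, a short-chain dehydrogenase-like gene (0.73, SE 0.10, adjusted p = 7.43e-06), and Cyb5a, the electron donor cytochrome b5 (0.50, SE 0.09, adjusted p = 0.00279). Htatip2 (ENSMUSG00000039745, chromosome 7, 49759115 to 49773975, plus strand) was at 22.9 ± 3.34 TPM in vehicle males and 38.5 ± 2.91 with the mixture. All 6 exposed libraries lay above the vehicle mean for each of the 6 genes. Of the AhR battery, 4 members rose (Cyp1a1, Cyp1a2, Htatip2 and Slc46a3), and 6 rose when adjusted over the list alone (camera adjusted p = 2.11e-19, and 8.38e-05 with an estimated correlation). Nqo1, a quinone reductase, Tiparp, an AhR feedback gene, and Cyp1b1 had log2 changes of 0.45, 0.31 and 0.13 that did not pass. In a fit of the LFD males alone 3 genes were called, and Cyp3a41a, Slc46a3 and Cyb5a were not. The Cyp3a41a call also ended without a filter on low values (adjusted p = 0.0903) and without the 3 libraries with muscle transcripts (0.0529).

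Further lists were higher as groups in the same males. The CAR/PXR list, targets of the xenobiotic receptors CAR and PXR, had 1 of 23 members risen (Cyp3a41a), 6 when adjusted over the list alone, and a median log2 change of 0.44 (camera adjusted p = 1.26e-13, and 0.000357 with an estimated correlation). Its members Cyp2b9 (1.39, SE 0.38), the exporter gene Abcc3 (0.78, SE 0.18) and Cyp2c29 (0.53, SE 0.16) did not pass over all genes. Of the 32 PPARα and fatty acid oxidation genes 0 passed over all genes and 13 rose when adjusted over the list alone (0.0281 with an estimated correlation). Values were 1.90 (SE 0.46) for the fatty acid hydroxylase Cyp4a14 and 0.33 (SE 0.09) for Cpt2, a mitochondrial carnitine palmitoyltransferase. Of the 32 female-biased liver genes 1 rose over all genes and 12 when adjusted over the list alone (median 0.58, 0.00507 with an estimated correlation), with Cyp2a4 at 1.37 (SE 0.34) and Sult2a1 at 1.14 (SE 0.30). Pericentral hepatocyte genes were also higher as a list (1 of 18 risen, Cyp1a2, and 5 when adjusted over the list alone, 0.0185 with an estimated correlation). De novo lipogenesis genes had a median of -0.53 and 0 of 22 called, with an adjusted p of 0.162 with an estimated correlation.

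In HFD males, 11 genes rose and 4 fell. Sult2a2 and Sult2a1, steroid and bile acid sulfotransferases more abundant in females, rose by 1.68 (SE 0.29, adjusted p = 0.0028) and 1.51 (SE 0.30, adjusted p = 0.0116). Sult2a2 was at 1.95 ± 0.769 TPM with vehicle and 9.77 ± 5.31 with the mixture, and 5 of 6 exposed libraries lay above the vehicle mean. Cystm1 rose by 0.97 (SE 0.18, adjusted p = 0.00954). Dpyd, the first enzyme of pyrimidine breakdown, fell by 0.41 (SE 0.09, adjusted p = 0.0404), and Serpinf1, which encodes the secreted protein PEDF, fell by 0.21 (SE 0.04, adjusted p = 0.0223). For 7 of the 8 genes that the naming rule picked, the Cyp1a genes among them, all 6 exposed libraries lay beyond the vehicle mean in the direction of the change. Without the 3 libraries with muscle transcripts (replicate 6 of this exposed group among them), 47 genes were called, 37 higher and 10 lower, including all 15. A fit of the HFD males alone called 1, Cyp1a2. The Serpinf1 call ended with scaling (adjusted p = 0.0505). The Dpyd call ended without a filter on low values (adjusted p = 0.0695) and with the replicate number as a block (0.0546).

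Amino acid and bile acid genes were lower as lists in these HFD males, with 0 members called over all genes in each. Of the 20 urea cycle and amino acid catabolism genes 11 fell when adjusted over the list alone (median -0.29, adjusted p = 0.018 with an estimated correlation), with Cps1, which fixes ammonia in the urea cycle, at -0.69 (SE 0.18) and Ass1 at -0.54 (SE 0.13). Of the 19 one-carbon and methionine cycle genes 8 fell when adjusted over the list alone (0.00775 with an estimated correlation), with the glycine methyltransferase gene Gnmt at -0.41 (SE 0.13) and Dmgdh at -0.29 (SE 0.08). Of the 23 bile acid genes 4 fell when adjusted over the list alone (0.00775 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.02 (SE 0.35) and the sterol transporter gene Abcg5 at -0.45 (SE 0.12). Stellate cell and fibrosis genes were higher by camera with the preset correlation (median 0.37, 12 of 24 risen when adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), with Lum at 0.64 (SE 0.15) and Col1a2 at 0.67 (SE 0.21). Lipid-associated macrophage genes had a median of 0.44 and 3 of 13 risen when adjusted over the list alone (adjusted p = 0.119 with an estimated correlation), with Spp1 at 0.93 (SE 0.28) and Trem2 at 0.55 (SE 0.20). Spp1 also stands in the cholangiocyte and ductular list, for which 4 of 100 splits gave a camera p as small (1.05e-05 with the preset correlation). Without the 3 libraries with muscle transcripts (replicate 6 of this exposed group among them), Spp1 (1.26, adjusted p = 0.0124), Trem2 (0.78, adjusted p = 0.0443) and Ass1 (-0.55, adjusted p = 0.0489) were called over all genes. The lipid-associated macrophage list had a mean log2(TPM + 1) of 4.05 and 4.02 in exposed replicates 2 and 6. Vehicle libraries had 3.84 to 4.24 and the other exposed libraries 4.45 to 5.12. Replicate 6, left out above, was the lowest of its group for that list. Stellate cell and fibrosis genes stood at 3.70 in exposed replicate 2, 3.57 to 3.76 with vehicle and 3.84 to 4.53 in the other exposed libraries. The AhR battery had 2 members risen (the Cyp1a genes), 3 when adjusted over the list alone (adjusted p = 0.069 with an estimated correlation). Beside these lists, hepatocyte core genes had a median of -0.10 (adjusted p = 0.1 with an estimated correlation).

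In LFD females, 6 genes rose and 0 fell by limma, with 1503 at an unadjusted p under 0.05. They included Htatip2, from 32.3 ± 4.28 to 57.9 ± 3.78 TPM (log2 change 0.83, SE 0.10, adjusted p = 2.89e-07), Cyb5a (0.48, SE 0.09, adjusted p = 0.00802) and Slc46a3 (0.74, SE 0.15, adjusted p = 0.0492). In each of the 5 named genes all 6 exposed libraries lay above all vehicle libraries. Of the genes called in LFD males 5 were among these 6. With scaling 3 genes were called, and the calls of Cyb5a and Slc46a3 ended (adjusted p = 0.174 for each). That of Slc46a3 also ended without the 3 libraries with muscle transcripts (0.131) and without a filter on low values (0.0905). In a fit of the LFD females alone both calls ended (adjusted p = 0.249 for Cyb5a and 0.227 for Slc46a3). The AhR battery had 4 members risen, also 4 when adjusted over the list alone (0.0475 with an estimated correlation). Gluconeogenesis and glycogen genes were lower as a list, with 1 of 19 fallen when adjusted over the list alone (0.0475 with an estimated correlation) and the glycogen phosphorylase gene Pygl at -0.31 (SE 0.13). Without those 3 libraries the p of the list Gluconeogenesis and glycogen was 0.473 with an estimated correlation. In HFD females the Cyp1a genes alone rose (limma, 670 genes at an unadjusted p under 0.05), and 4 genes were called without the 3 libraries with muscle transcripts, which lie outside these groups and enter the shared spread. Htatip2 was among them (adjusted p = 0.0496). Htatip2 had a log2 change of 0.46 (SE 0.10, adjusted p = 0.0801 with all libraries). Of the lists, the AhR battery had 2 members risen and 4 when adjusted over the list alone (adjusted p = 0.0995 with an estimated correlation). Interferon response genes had a median of 0.21 and 0 of 34 called, also when adjusted over the list alone (adjusted p = 0.604 with an estimated correlation).

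Averaged over both sexes and both diets, 15 genes rose with the mixture and 0 fell by limma, with 1850 at an unadjusted p under 0.05. Beside Cyp1a1 (mean log2 change 3.31, SE 0.10) and Cyp1a2 (2.51, SE 0.06), these were led by Ugt1a9, a glucuronosyltransferase gene (0.96, SE 0.13, adjusted p = 1.79e-05), Pcp4l1 (0.78, SE 0.14, adjusted p = 0.00364), Sult2a2 (0.67, SE 0.14, adjusted p = 0.0303) and Slc46a3 (0.66, SE 0.08, adjusted p = 2.87e-07). The mean of Sult2a2 came from the males, with log2 changes of 1.03 (LFD) and 1.68 (HFD), against 0.03 and -0.06 in females. Ugt1a9 spans 88070800 to 88218997 of chromosome 1 and overlaps Ugt1a1, Ugt1a5, Ugt1a6a, Ugt1a6b and Ugt1a7c, with which it shares exons, so its value rests on how shared reads were assigned. Its log2 change was 0.81 or more in each of the 4 combinations, while Ugt1a1 had a mean log2 change of 0.03 (SE 0.06). The AhR battery had 4 members risen and 8 when adjusted over the list alone (0.000355 with an estimated correlation). Gluconeogenesis and glycogen genes were lower as a list (0 called over all genes, 1 when adjusted over the list alone, 0.0262 with an estimated correlation), and for the list Gluconeogenesis and glycogen that p was 0.205 without the 3 libraries with muscle transcripts. With scaling 8 genes were called, all among the 15, and Sult2a2 was not one of them (adjusted p = 0.0673). Its call also ended without a filter on low values (adjusted p = 0.0693) and without the 3 libraries with muscle transcripts (0.066).

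The next question was whether the response to the mixture differed by diet. Cyp1a1 rose less on the HFD in both sexes, with a difference of log2 changes of -4.08 in males (SE 0.29, limma adjusted p = 1.51e-13) and -3.75 in females (SE 0.29, adjusted p = 2.76e-12). If the diets were run as separate cohorts, cohort and diet cannot be told apart in such differences. By limma 1 gene was called in each sex, Cyp1a1, with 1158 and 734 genes at an unadjusted p under 0.05, and without a filter on low values 2 were called in males. In males, 5 lists responded differently by diet with an estimated correlation, with lower changes on the HFD than on the LFD and 0 members called over all genes. The CAR/PXR list had a median difference of -0.61 (3 of 23 lower when adjusted over the list alone, 0.00158 with an estimated correlation), with Cyp2c29, a P450 of pericentral hepatocytes, at -1.04 (SE 0.22). The other 4 had an adjusted p of 0.026 with an estimated correlation. Urea cycle and amino acid catabolism had a median of -0.45 and 10 of 20 lower when adjusted over the list alone, with Ass1 at -0.62 (SE 0.19). Pericentral hepatocyte genes had a median of -0.32 and 3 of 18 lower when adjusted over the list alone, with Oat at -1.15 (SE 0.27) and Cyp2e1 at -0.59 (SE 0.19). Bile acid genes and one-carbon genes had medians of -0.20 and -0.18, and 0 members were called when adjusted over the list alone. Stellate cell and fibrosis genes had a median of 0.54 and 11 of 24 higher when adjusted over the list alone (adjusted p = 0.0965 with an estimated correlation), with Lum at 0.93 (SE 0.22). Without the 3 libraries with muscle transcripts, which include replicate 6 of the exposed HFD males, 12 genes differed in males, among them Cyp2c29 (-1.18) and Oat (-1.27). In females 0 lists were called with an estimated correlation.

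For the response by sex, 0 genes differed on the LFD and 0 on the HFD by limma, with 673 and 740 genes at an unadjusted p under 0.05. On the LFD the CAR/PXR list responded more in males, with a median difference of 0.43 and 1 of 23 members higher when adjusted over the list alone (0.0147 with an estimated correlation). Its members Cyp3a41a and Abcc3 had differences of 1.36 (SE 0.35) and 0.72 (SE 0.25). Female-biased liver genes had 4 of 32 higher when adjusted over the list alone (adjusted p = 0.0589 with an estimated correlation). On the HFD 0 lists were called with an estimated correlation. Across the 15820 genes, the log2 changes with the mixture in LFD males and LFD females had a correlation of 0.197 (0.2 by ranks), and those in HFD males and HFD females one of -0.037 (0.04 by ranks), in groups that share no library. Genes are not independent replicates, so no p is given.

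The comparison of diets called far more genes. The animals of each diet were numbered separately, so if the diets were run as separate cohorts, diet and cohort cannot be told apart in any comparison of diets given here. In vehicle males, 4963 genes changed with the HFD, 4043 higher and 920 lower. With scaling the split was 2071 higher and 1823 lower, and the median log2 change of all genes moved from 0.11 to -0.003, so small increases depend on the scaling. Genes of lipid storage rose. Cidea (ENSMUSG00000024526, chromosome 18, 67343604 to 67367785, plus strand), which promotes fusion of lipid droplets, went from 1.58 ± 1.70 to 107 ± 23.4 TPM (log2 change 5.62, SE 0.54, adjusted p = 4.85e-11), and its relative Cidec rose by 4.38 (SE 0.38). Cyp2b9, a P450 more abundant in females, went from 1.46 ± 0.365 to 159 ± 128 TPM (5.47, SE 0.38). Sult1e1, an estrogen sulfotransferase, rose by 4.50 (SE 0.55), and Cfd and Cyp2a22 rose by 4.22 and 4.01. Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252, minus strand), a steroid-reducing enzyme, went from 394 ± 60.6 to 22.6 ± 45.3 TPM (log2 change -5.71, SE 0.55, adjusted p = 6.86e-11) and Serpina1e, an α1-antitrypsin, from 6945 ± 2831 to 356 ± 462 (-4.93, SE 0.55). Replicate 1 of the HFD group held 115 TPM of Hsd3b5 and 1287 of Serpina1e, while the other 5 held at most 9.62 and 260. Moxd1, Tff3, Fabp5 and Mup7, a major urinary protein gene, fell by 5.48, 4.14, 4.12 and 4.05. For 11 of these 12 genes, picked for large changes in the same libraries, the groups did not overlap, the exception being Mup7.

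In these males, of the 20 lipid droplet and steatosis genes 19 rose, also 19 when adjusted over the list alone (adjusted p = 0.0118 with an estimated correlation). Examples were the fatty acid transporter gene Cd36 (2.97, SE 0.23) and Mogat1 (3.26, SE 0.28). Of the 23 CAR/PXR genes 16 rose, 18 when adjusted over the list alone (0.0118), among them Cyp3a11 (2.56, SE 0.22). Of the 28 male-biased genes 25 fell, 26 when adjusted over the list alone (0.0118, median -1.54), among them Selenbp2 (-3.46, SE 0.36). Of the 20 hepatocyte core genes 11 fell, 13 when adjusted over the list alone, by a smaller amount (0.012, median -0.24), among them Apoa1 (-0.85, SE 0.15). Of 100 splits of these libraries, 2 gave the lipid droplet list a camera p as small, 4 the CAR/PXR list, 5 the male-biased list and 7 the hepatocyte core list. With scaling these medians were 1.29 for lipid droplet and steatosis genes, 0.75 for CAR/PXR targets, -1.69 for male-biased liver genes and -0.39 for the hepatocyte core list. The next lists were called with the preset correlation only. Of the 32 PPARα genes 26 rose, 27 when adjusted over the list alone (adjusted p = 0.0706 with an estimated correlation), such as Acot2 (2.60) and Vnn1 (2.52). Of the 24 cholesterol synthesis genes 20 fell, 22 when adjusted over the list alone (adjusted p = 0.0659 with an estimated correlation), with Sqle at -3.47 (SE 0.37) and Fdps at -2.56 (SE 0.36). All 13 heat shock genes rose (adjusted p = 0.0893 with an estimated correlation), with Hspb1 at 1.90 (SE 0.18). Of the 24 stellate cell and fibrosis genes 21 rose (adjusted p = 0.144 with an estimated correlation), with Col1a1 at 2.20 (SE 0.28) and Timp1 at 1.77 (SE 0.23). Female-biased genes had 17 of 32 risen (adjusted p = 0.185 with an estimated correlation), and Slc22a27 rose by 3.19 (SE 0.30). Nrf2 targets had 17 of 22 risen and 2 fallen (adjusted p = 0.138 with an estimated correlation), with Gstm3 at 2.54. Inflammatory chemokine and cytokine genes had 12 of 19 risen and 1 fallen (adjusted p = 0.152 with an estimated correlation), with Ccl2 at 2.24 (SE 0.26). Macrophage genes had 11 of 19 risen (adjusted p = 0.638 with an estimated correlation), with Itgax at 1.06 (SE 0.18).

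**Figure D3:**
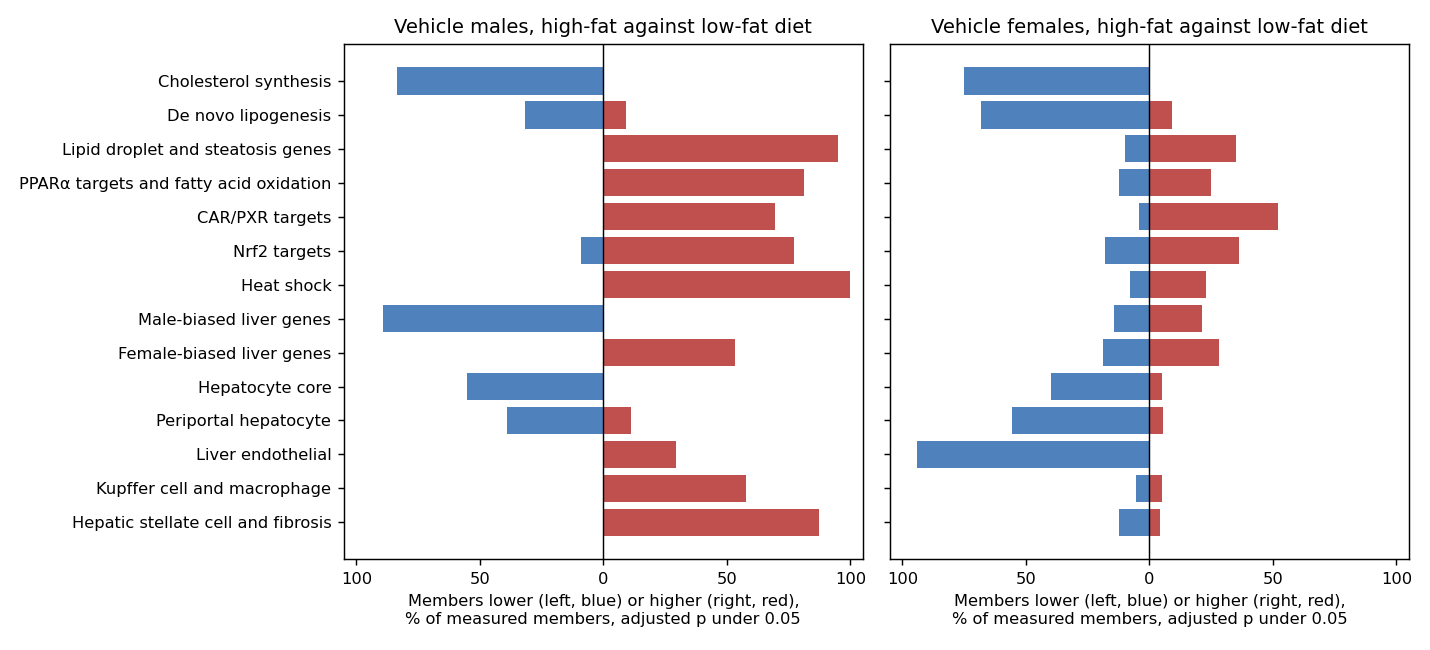
Share of the measured members of 14 gene lists that were higher (red, right) or lower (blue, left) on the HFD than on the LFD at a limma adjusted p under 0.05, in percent of members, in vehicle males and vehicle females (6 livers per group). Lipid droplet genes (19 of 20) and heat shock genes (13 of 13) were higher in males, endothelial genes were lower in females (16 of 17), cholesterol synthesis genes were lower in both (20 and 18 of 24), and the 5 Liver endothelial genes higher in males became 3 higher and 1 lower with scaling of TPM (median -0.007).

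In vehicle females, 4424 genes changed with the HFD, 2281 higher and 2143 lower. Sult2a7, a sulfotransferase, went from 5.73 ± 4.59 to 91.8 ± 23.0 TPM (log2 change 3.96, SE 0.28, adjusted p = 3.28e-14), and Cyp26a1 (ENSMUSG00000024987, chromosome 19, 37697798 to 37701536, plus strand), which clears retinoic acid, from 8.30 ± 2.89 to 100.2 ± 28.6 (3.47, SE 0.34, adjusted p = 1.8e-10). Adam11, Raet1d, Sult2a5 and the acute phase gene Orm3 rose by 3.19, 3.19, 3.09 and 3.03. Fabp5 (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607, plus strand), a fatty acid binding protein, went from 196 ± 56.8 to 9.05 ± 3.04 TPM (log2 change -4.30, SE 0.35, adjusted p = 1.52e-12). The squalene epoxidase gene Sqle went from 45.9 ± 27.6 to 3.95 ± 1.04 TPM (-3.09, SE 0.37). Cyp3a44, G6pdx, Idi1 and Chrna4 fell by 4.23, 3.42, 3.02 and 3.00. For all 12 of these genes, picked for large changes in the same libraries, the groups did not overlap.

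No list kept its call in these females with an estimated correlation, so the following describes calls with the preset correlation. Of the 24 cholesterol synthesis genes 18 fell, 20 when adjusted over the list alone, with Cyp51 at -2.44 (SE 0.31), and of the 17 endothelial genes 16 fell, with Stab1, a scavenger receptor, at -0.85 (SE 0.13) and Eng at -0.61 (SE 0.08). Both had an adjusted p of 0.292 with an estimated correlation, as had the CAR/PXR list (12 of 23 risen and 1 fallen, with Cyp2c50 at 2.11) and the retinoid list (9 of 18 risen and 3 fallen, with Aldh1a1 at 2.11, SE 0.13). Of the 22 de novo lipogenesis genes 15 fell and 2 rose (adjusted p = 0.651 with an estimated correlation). Acss2 fell by 2.59, Lpin1 by 2.96 and Acaca, which makes malonyl-CoA, by 2.29, while Srebf1, which encodes the lipogenic regulator SREBP1, rose by 1.45 (SE 0.17). Periportal genes fell in 10 of 18 and rose in 1, with Cps1 at -1.01 (SE 0.18), and pericentral genes rose in 9 of 18 and fell in 1, with Cyp7a1 at 2.51 (SE 0.35). Each had an adjusted p of 0.589 with an estimated correlation. Adjusted over the list alone, 16 endothelial, 15 lipogenesis and 11 periportal genes fell, and 12 CAR/PXR, 9 retinoid and 9 pericentral genes rose.

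In males given the mixture, the HFD changed 6105 genes, 5010 higher and 1095 lower. With scaling 2473 were higher and 2551 lower, and the median of all genes moved from 0.15 to -0.006. Cidea, Ly6d, Cidec, Cyp2b9, Orm3 and Lcn2 rose by 5.87, 4.81, 4.69, 4.34, 4.28 and 4.19, and Hsd3b5, Serpina1e, Mup7, Cyp1a1, Moxd1 and Mup11 fell by 6.26, 5.65, 4.65, 4.65, 3.81 and 3.46. Stellate cell and fibrosis genes rose in 23 of 24 members, 24 when adjusted over the list alone (median 1.35, adjusted p = 0.0351 with an estimated correlation). Col1a1 went from 3.98 ± 0.740 to 48.8 ± 27.1 TPM (log2 change 3.15, SE 0.28) and Col3a1 rose by 2.72 (SE 0.23). Lipid droplet genes rose in 18 of 20 (0.032), male-biased genes fell in 25 of 28 (0.0106), hepatocyte core genes fell in 13 of 20 and rose in 1 (0.00856), periportal genes fell in 12 of 18 and rose in 1 (0.032), and complement and coagulation genes fell in 18 of 27 (0.0289), with C8b at -3.19 (SE 0.31) and F11 at -1.40 (SE 0.13). Each of these p-values is with an estimated correlation. Adjusted over the list alone, 18 lipid droplet genes rose, and 26 male-biased, 13 hepatocyte core, 12 periportal and 19 complement and coagulation genes fell. Of 100 splits, 9 gave the periportal list a camera p as small, 3 the male-biased list, 3 the complement and coagulation list, and 1, the real one, the other 3 lists. With scaling the medians were 1.21 for the list Hepatic stellate cell and fibrosis, 1.39 for Lipid droplet and steatosis genes and -1.80 for Male-biased liver genes. Cell cycle genes rose in 21 of 23 (adjusted p = 0.272 with an estimated correlation), with Mcm2 at 1.20 (SE 0.15). Lipid-associated macrophage genes rose in 11 of 13 and fell in 1 (adjusted p = 0.121 with an estimated correlation), with Gpnmb at 2.51 and Cd63 at 2.57. The vehicle and exposed male comparisons share no library, and 3238 genes were higher and 596 lower in both, against 1280.4 and 63.7 for independent lists.

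In females given the mixture, the HFD changed 3039 genes, 1814 higher and 1225 lower. Sult2a7, Cyp26a1, Gsta2, Adam11, Orm3 and Sult2a3 rose by 3.43, 3.31, 3.12, 3.09, 2.99 and 2.81, and Cyp1a1, Fabp5, Eif4ebp3, Cyp3a44, Sult3a1 and G6pdx fell by 4.33, 3.49, 2.92, 2.66, 2.65 and 2.63. With the preset correlation, cholesterol synthesis genes were lower (15 of 24 fallen, with Idi1 at -2.56), retinoid genes were higher (7 of 18 risen and 2 fallen, with Aldh1a1 at 1.95), and both had an adjusted p of 0.441 with an estimated correlation. Interferon response genes rose in 14 of 34 and fell in 1 (adjusted p = 0.53 with an estimated correlation), with Ifit3 at 1.01 (SE 0.19) and Stat2 at -0.49 (SE 0.10). Endothelial genes fell in 7 of 17 (adjusted p = 0.474 with an estimated correlation), with Stab1 at -0.47. Adjusted over the list alone, 16 cholesterol and 9 endothelial genes fell, and 9 retinoid and 18 interferon genes rose. Vehicle and exposed females shared 1411 genes higher and 911 lower, against 261.6 and 165.9 for independent lists.

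The effect of diet differed between the sexes in vehicle animals for 2887 genes, 2338 with a higher log2 change in males and 549 with a lower one. With scaling the split was 1069 and 1031, and the median difference over all genes moved from 0.12 to -0.007. The largest positive differences were in Cidea (5.41, SE 0.76, adjusted p = 2.57e-06), Cyp2b9 (5.32), Cyp3a44 (4.27), the cell cycle inhibitor gene Cdkn1a (4.14), Cyp4a14 (4.08) and Cyp2a4 (3.46). The largest negative ones were in Moxd1 (-5.15), Mup17 (-4.21), Tff3 (-4.10), Hsd3b5 (-3.85), Sult2a7 (-3.80) and Mup16 (-3.72). Male-biased genes were lower in this difference for 23 of 28 members, 26 when adjusted over the list alone (median -1.84, 0.021 with an estimated correlation), among them Cyp7b1 (-2.64, SE 0.33) and Susd4 (-2.32, SE 0.27). Further lists were called with the preset correlation only, each with an adjusted p of 0.236 with an estimated correlation. Endothelial genes had a higher change in males for 15 of 17 (Stab1 at 0.98, SE 0.18), stellate cell and fibrosis genes for 21 of 24 (Col4a1 at 1.51, SE 0.24), heat shock genes for 9 of 13 (Hsph1 at 1.61, SE 0.32), and PPARα genes for 22 of 32 with 1 lower (Plin5 at 2.26, SE 0.29). Adjusted over the list alone, these were 16, 21, 11 and 26. With scaling, 13 members of the list Liver endothelial had a higher change in males (median 0.63) and 14 of Hepatic stellate cell and fibrosis (median 0.67), and the median of Male-biased liver genes was -1.99. Genes higher on the HFD in vehicle animals of both sexes numbered 1374, and genes lower in both 357, against 582.9 and 124.6 for independent lists. Genes higher on the HFD in vehicle males and lower in vehicle females numbered 249. These counts were taken without scaling, on which small increases in males depend.

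The sexes were compared on the LFD with vehicle as a reference for these lists. Of 3752 genes that differed, 1045 were higher in males and 2707 in females, and with scaling 1792 and 1641. Mup20 (ENSMUSG00000078672, chromosome 4, 62050234 to 62054158, minus strand), which encodes the male pheromone darcin, was at 11053 ± 1691 TPM in males and 137 ± 25.0 in females (log2 difference 6.33, SE 0.28, adjusted p = 1.06e-22). Cyp2a4, a steroid hydroxylase, was at 4.80 ± 1.17 TPM in males and 1724 ± 541 in females (-8.16, SE 0.34, adjusted p = 1.77e-23). Mup7, Mup14, Cyp4a12a, Serpina1e and Mup11 were higher in males by 7.32, 6.71, 6.26, 6.18 and 5.94. Cyp2b9, Cyp3a41a, Sult2a2 and Cyp2c69 had differences of -7.88, -7.87, -7.39 and -7.36. Of the 28 male-biased genes 27 were higher in males, 28 when adjusted over the list alone (1.32e-05 with an estimated correlation), and all 32 female-biased genes were lower (1.39e-07). CAR/PXR genes were lower in males for 14 of 23 and higher for 2 (0.00128 with an estimated correlation), with Cyp2b13 at -6.42. Endothelial genes were lower in males for 15 of 17 (adjusted p = 0.233 with an estimated correlation), with Lyve1 at -1.51 (SE 0.23). Kupffer cell genes were lower for 14 of 19 (adjusted p = 0.588 with an estimated correlation), with Cd163 at -1.57 (SE 0.23). Adjusted over the list alone, 32 female-biased, 17 CAR/PXR, 16 endothelial and 14 Kupffer cell genes were lower in males. For complement and coagulation genes camera and the median differed in sign (higher in males by camera, adjusted p = 0.0124, and 0.699 with an estimated correlation, with a median of -0.04).

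**Figure D4:**
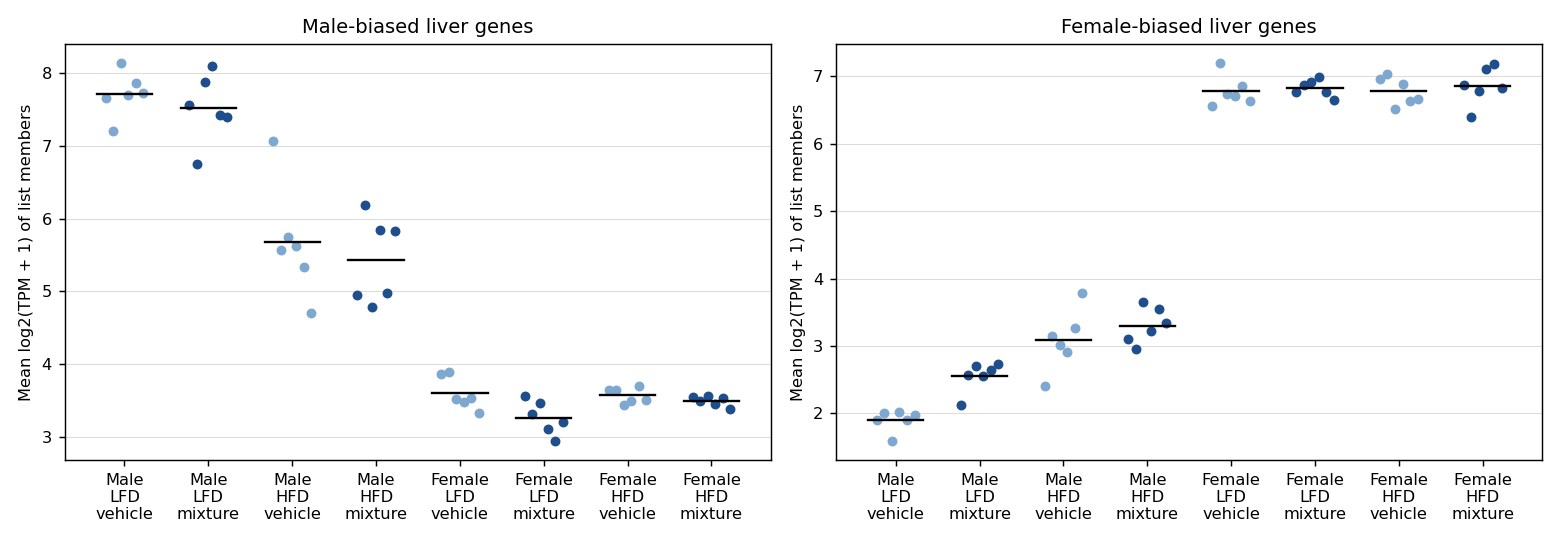
Mean log2(TPM + 1) of the measured members of the male-biased (left, 28 genes) and female-biased (right, 32 genes) lists in each liver library, with a point per library and a line at the group mean (n = 6 per group, light points for vehicle and dark for the mixture). Male-biased members fell on the HFD in males (25 of 28 in vehicle animals), and female-biased members were higher there in 17 of 32.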

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

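The tests of explanations and the splits of libraries in this part were chosen after the results were seen, while the tests of differences between groups were planned.

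The first pattern is Cyp1a1, a target of the dioxin receptor, which rose less with the mixture on the high-fat diet (HFD) than on the low-fat diet (LFD). A test of the difference singled it out, with -4.08 in males and -3.75 in females on the log2 scale. Scaling of the libraries leaves the difference nearer 0 at -3.762, which argues against it as the whole cause. A pseudocount of 0.1, which compresses low values less, leaves it at -3.695, which argues against that cause as well. A weaker response to the mixture as a whole on the HFD stays open: of 28 combinations of the other 14 genes called in the mean over strata with a sex, 19 had the smaller change on the HFD (6 of 14 in males and 13 of 14 in females). Cyp1a2 rose by 2.32 in HFD males and 2.24 in LFD males, so a loss of response in every target is not what was seen in males. If the diets were run as separate cohorts, cohort and diet cannot be told apart in this difference. Uptake or tissue level of the compounds was not measured in the values used here, so no biological explanation was tested further.

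The second pattern is skeletal muscle transcripts in 3 libraries. The 15 summed genes had a median of 28.5 TPM in the other 45 libraries and reached 25913 TPM in replicate 6 of the HFD males given the mixture, with Acta1 at 6062, Mb at 2836 and Ckm at 1336. Muscle carried over with the liver is a candidate source: of 16 muscle genes not in that sum, at least 15 lay above all other 45 libraries in each of the 3. Replicate 4 of the LFD vehicle males, at 811 TPM, had 15 of these 16 above the rest of the 45. The pattern is therefore not confined to the 3. A response of liver to the mixture is argued against, since 2 of 24 exposed libraries and 1 of 24 vehicle libraries exceeded 1000 TPM. The labels name no step that would exclude other tissue, and no biological explanation was tested beyond the mixture.

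The third pattern is the fall of male-biased genes in males on the HFD. Scaling of the libraries is argued against, as the median of the male-biased list with scaling was -1.688 in vehicle males. A lower share of hepatocytes is argued against as the whole cause, since the hepatocyte core list had a median of -0.24. A shift of males toward the female pattern may be part of it: with scaling, 70.4% of 206 genes higher in vehicle LFD females were higher on the HFD in exposed males, against 49.1% of all genes, in groups that share no library. Those genes were chosen for a lower level in LFD males than in females. Genes at low TPM have more room to rise than to fall. Genes of a like level in males were not compared, so this share alone cannot decide for such a shift. Chance can be excluded for the fall of the list, whose mean log2(TPM + 1) per library separated the diets without overlap in 2 comparisons that share no library. It was at least 7.20 on the LFD and at most 7.07 on the HFD in vehicle males, and at least 6.75 and at most 6.18 in exposed males. The size of the camera p is less certain, as 5 of 100 splits gave one as small in vehicle males and 3 of 100 in exposed males. The shift was found and tested on the same data and stays a hypothesis. Hormones were not measured in the values used here.

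Differences of the effect of diet between the sexes were called for 2887 genes. On the log2 scale they were 5.41 for Cidea, 5.32 for Cyp2b9, 4.27 for Cyp3a44, 4.14 for Cdkn1a, 4.08 for Cyp4a14 and 3.46 for Cyp2a4. On the lower side they were -5.15 for Moxd1, -4.21 for Mup17, -4.1 for Tff3, -3.85 for Hsd3b5, -3.8 for Sult2a7 and -3.72 for Mup16, and the male-biased list had a median of -1.84. The effect of the mixture differed by diet in males for 5 lists, with medians of -0.612 for CAR/PXR targets, -0.205 for bile acid genes, -0.178 for one-carbon genes, -0.452 for urea cycle genes and -0.324 for pericentral genes. By sex on the LFD it differed for CAR/PXR targets, with a median of 0.426.

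Single libraries lay far from the other 5 of their group in 5 of 44 groups of values tested. Chance gives about 2.2 if TPM values are normally distributed and the groups of values independent. That was not checked, and Hsd3b5 and Serpina1e were flagged in the same library, so no excess over chance is claimed. The gap to the nearest library as a share of the range was 0.926 for Hsd3b5 and 0.826 for Serpina1e, both in replicate 1 of the HFD vehicle males (115 and 1287 TPM). It was 0.754 for Htatip2 in replicate 1 of the LFD vehicle females (23.8 TPM, others 32.8 to 35.7), 0.68 for Sult2a7 in replicate 2 of that group (14.7 TPM, others at most 6.40) and 0.764 for Sqle in replicate 4 of the HFD vehicle females (1.89 TPM, others 3.99 to 4.64).

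Other splits of the same libraries were fitted, 100 per comparison with the real one included. Apart from diet by sex, chance can be excluded for the counts of genes in these comparisons, each reached by the real split alone. For the effect of diet the real counts and the highest of the other splits were 4963 and 2032 in vehicle males (1 of 100), 4424 and 1471 in vehicle females (1), 6105 and 3795 in exposed males (1) and 3039 and 1265 in exposed females (1). They were 3752 and 1640 for sex (1) and 15 and 2 for the mixture over all strata (1). For diet by sex they were 2887 and 1733 (1). Those splits exchange diet labels within each sex, which removes the diet effect as well as its difference between the sexes. They therefore cannot exclude chance for the difference. For the mixture in HFD males, 4 of 100 splits reached the real count of 15, but another split called 106, so chance is not taken as excluded there.

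Chance cannot be excluded for the next counts of genes, although the Cyp1a genes were separated without overlap. The mixture called 6 genes in LFD males (9 of 100 splits as large, highest other 108), 6 in LFD females (5, highest 42) and 2 in HFD females (5, highest 3). Mixture by diet called 1 gene in males (10, highest 75) and 1 in females (11, highest 7). Any split that calls a gene reaches a count of 1, so these splits do not weigh the difference of Cyp1a1 itself. For mixture by sex the real counts were 0 by limma (673 genes on the LFD and 740 on the HFD at an unadjusted p under 0.05), which all 100 of 100 splits reach, so the splits decide nothing there. The highest others were 15 and 139. Some splits called far more than the real count, such as 108 against 6, 106 against 15 and 139 against 0. The cause of this was not tested.

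The number of lists called by camera with the preset correlation was 25 for mixture by diet in males (1 of 100, highest other 24). The margin is 1 list, and those splits also remove the effect of the mixture itself, so chance is not taken as excluded there. For diet in exposed females, 2 of 100 splits reached the real count of 20 lists, but the highest other also called 20, so chance is not taken as excluded there. It cannot be excluded for the mixture in LFD males (14 lists, 27 of 100, highest 18), HFD males (20, 18 of 100, highest 25), LFD females (10, 72 of 100, highest 22), HFD females (13, 10 of 100, highest 17) or all strata (16, 12 of 100, highest 25). Nor can it be for diet in vehicle males (20, 13 of 100, highest 23), vehicle females (14, 16 of 100, highest 19) or exposed males (24, 11 of 100, highest 26). The same holds for mixture by diet in females (11, 48 of 100, highest 22), mixture by sex on the LFD (10, 62 of 100, highest 22) and HFD (19, 6 of 100, highest 25), diet by sex (19, 10 of 100, highest 23) and sex (14, 35 of 100, highest 21).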

How the results depend on the processing

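Fits without the 3 libraries with muscle transcripts, and scaling of the lists, were chosen after the data were seen, and the other alternatives were chosen before the data were examined.

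Without the 3 libraries with muscle transcripts (replicate 6 of the exposed HFD males, and replicate 3 of the vehicle and of the exposed LFD females), 47 genes instead of 15 changed with the mixture in HFD males, 4 instead of 2 in HFD females, and 12 instead of 1 differed by diet in males. A fit of only the groups compared gave 3 instead of 6 in LFD males and 1 instead of 15 in HFD males, with fewer libraries behind the spread. Scaling gave 3 instead of 6 in LFD females and 8 instead of 15 over all strata. Without a filter 2 genes instead of 1 differed by diet in males. For these the cause was not tested. With the replicate number as a block, 4 genes instead of 1 differed by diet in males, and the Dpyd call in HFD males ended (log2 change -0.41, adjusted p = 0.0546). No label says that the numbers pair the animals, and residuals of same-numbered libraries had r between -0.207 and 0.438. Their means were weak, though mostly positive. The highest mean was 0.156 (-0.028 for other pairs), between vehicle and exposed LFD females, where replicate 3 of both groups held muscle transcripts. Residuals cancel out within a group, so the mean of other pairs follows from that of same-numbered pairs and is no separate baseline. A weak link between same-numbered libraries stays open.

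With an estimated correlation between genes, fewer lists were called by camera. For the mixture these were 5 instead of 14 in LFD males, 3 instead of 20 in HFD males, 2 instead of 10 in LFD females, 0 instead of 13 in HFD females and 2 instead of 16 over all strata. For diet they were 4 instead of 20 in vehicle males, 0 instead of 14 in vehicle females, 6 instead of 24 in exposed males and 0 instead of 20 in exposed females. For mixture by diet they were 5 instead of 25 in males and 0 instead of 11 in females, and for mixture by sex 1 instead of 10 on the LFD and 0 instead of 19 on the HFD. For diet by sex it was 1 instead of 19 and for sex 4 instead of 14. The estimate widens the spread of a list whose genes vary together.

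Of 270 log2 changes of 131 named genes, none of those called turned around under these alternatives. The call and direction were the same for 266 with scaling, 266 without a filter, 268 with a pseudocount of 0.1, 251 with only the groups compared (where the mean over strata was not fitted), 269 with the block and 260 without the 3 libraries. Scd2 in LFD females, which was not called, had a log2 change of -0.222 without them, against 0.12. The alternatives that need counts were not run, because the table holds TPM. Depth is unknown, so what it limits could not be computed.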

Other observations

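The test of a hypothesis in this part, and the values of single libraries, were chosen after the data were seen.

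Saa1, an acute phase gene, was at 2422 TPM in replicate 6 of the HFD males given the mixture, the library with the most muscle transcripts, while the highest of the 45 libraries other than the 3 with the most muscle transcripts had 532. Replicate 3 of the LFD females given the mixture, which held adrenal cortex transcripts, also held 46.0 TPM of the adipocyte gene Adipoq, against at most 9.48 in those 45 libraries.

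Most genes called for diet both with and without the mixture changed in one direction, which does not test whether the size of the change was alike. In females, 0 genes that changed with diet in both the vehicle and the exposed comparison went opposite ways, and in males 3 did. Across genes the correlation of the log2 changes was 0.764 in females and 0.754 in males, and genes are not independent replicates. Between vehicle males and vehicle females more genes went the same way, 1374 higher and 357 lower in both, against 582.9 and 124.6 for independent lists. Without scaling 294 genes went opposite ways, 45 of them lower in males and higher in females. The same-way counts were also taken without scaling.

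In LFD males, 75% of the 100 genes that were higher in females than in males among HFD vehicle animals (by a log2 difference of at least 1) lay on the higher side with the mixture, against 48.4% of all genes. A shift of LFD males toward the female pattern may account for it, but 8 of 100 splits of the 12 libraries gave a share as large and the highest other was 82%, so chance cannot be excluded for this share. For the female-biased list, fixed before the data were seen, the real split alone gave a camera p as small (1.89e-20, smallest other 5.31e-12, and adjusted p = 0.00507 with an estimated correlation). On the other side, 61.7% of the 133 genes higher in males among HFD vehicle animals were lower with the mixture, against 51.4% of all genes. Both shares are of genes chosen for their level in 1 sex, and genes of a like level in males were not compared. They alone therefore cannot decide for such a shift. For the male-biased list, also fixed before the data were seen, 44 of 100 splits gave a camera p as small (0.0137). The hypothesis stays open.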
